A study of Homo sapiens with 36 samples.

How the data were processed

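The series measured gene expression by RNA sequencing in human pancreatic ductal adenocarcinoma cells given ligands of the liver X receptors (LXR), which are nuclear receptors for oxysterols. The 36 libraries came from 3 established lines, BxPC-3, MIA PaCa-2 and PANC-1. Each line received the vehicle DMSO, the synthetic LXR agonist GW3965, or 1 of 2 compounds known here only by the code names 1E5 and 3A4, which the labels call LXR inverse agonists. Ligands were given at 10 µM for 48 h, per the labels' protocols. BxPC-3 was grown in RPMI 1640 and the other lines in DMEM, both with 10% fetal bovine serum at 37 °C and 5% CO2, so line and medium cannot be separated. Per the same protocols, RNA was purified on columns and 500 ng of total RNA entered a stranded total RNA library kit. Each of the 12 groups held 3 libraries that the titles call biological replicates. The labels do not say whether these came from separate cultures, so the p-values measure the spread between these libraries.

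The authors deposited 1 table of whole-number counts per gene for all 36 libraries. Trim Galore 0.4.4, HISAT2 2.0.2, SAMtools 1.3 and StringTie 1.3.1c are named, with the build GRCh38, in the submitters' processing notes, without their roles or order. The annotation, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Gene counts that come from StringTie are derived from coverage, and reads at a locus shared by overlapping genes can be split between them. Genes read through from one locus into the next, pseudogenes and antisense genes are therefore reported as uncertain. The table had 58658 lines. The 407 lines that named a transcript and 8 that named an assembled locus without a gene were left out, which removed at most 0.00396% of the counts of a library. Of the 58243 genes kept, 57532 had a symbol in the file. Gene types and chromosomes were taken from GENCODE release 29.

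Counts were analysed as deposited. Within each line, edgeR 4.0.16 in R 4.3.3 was fitted to the 12 libraries with 1 mean per group, TMM scaling and filterByExpr at its defaults (a count of about 10 in enough libraries and a total of at least 15). This left 18042 genes in BxPC-3, 16254 in MIA PaCa-2 and 18544 in PANC-1. The quasi-likelihood test was two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Levels are CPM, counts divided by the TMM-scaled library total in units of 1e+06, as mean ± SD of 3 libraries, and log2 fold changes are given with standard errors (SE). Where all libraries of a group had a count of 0, the fold is given as a lower bound. It is the mean of the other group divided by 3 counts over the summed totals of the group at 0. Such bounds cover only the counting error of the group at 0, and not the spread between the libraries of either group. The 95% intervals of differences cover only the spread and counting error of these libraries. Responses that differ among lines were tested in 1 fit of all 36 libraries over 22132 genes, with an F test of 2 degrees of freedom on the ligand by line interaction.

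Lists of 25 gene groups, with 427 genes, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Their names are LXR targets, cholesterol synthesis and uptake, fatty acid synthesis, integrated stress response, endoplasmic reticulum (ER) chaperones, mitosis, DNA replication, apoptosis, p53 targets, interferon response, NF-kB and chemokines, glycolysis and hypoxia, NRF2 targets, AHR and xenobiotic targets, PPAR targets and lipid droplets, lysosome and autophagy, epithelial, mesenchymal, classical pancreatic tumour, basal-like pancreatic tumour, immediate early, ribosomal proteins, other cell types, mitochondrially encoded, and replication-dependent histones. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 222 tests of lists with at least 3 measured genes. Camera with an estimated correlation was run beside it. Fry, which tests a list without setting it against the other genes, was also run and is given only where named. Members past the threshold are counted over all genes and adjusted over the list alone.

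The named genes were, in every contrast, ABCA1, ABCG1, SREBF1, MYLIP, SCD, FASN and the receptor genes NR1H2 and NR1H3. To these were added, per contrast, the 4 highest and 4 lowest fold changes among called genes with a mean of at least 2 CPM and no overlap between groups. Up to 6 genes per direction called in all 3 lines, up to 3 called members per list that passed camera, and the 4 genes with the smallest p for a difference among lines completed the rule. Genes on chromosome Y and XIST were not named. Genes outside the rule are marked where they appear.

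The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 36 libraries in 1 fit, only the libraries of the groups compared, and leaving out each library in turn. Others were added after the data were seen and are named in the closing section. All steps were tested on simulated counts drawn from the means, spreads and depths of these libraries, with 100 genes changed 2-fold and 100 changed 4-fold. In the simulated contrasts against DMSO, edgeR recovered 62% to 64% of the 2-fold changes in BxPC-3, 39% to 44% in MIA PaCa-2 and 50% to 61% in PANC-1. It recovered 85% to 97% of the 4-fold changes in the 9 contrasts, with 3 to 10 false calls among 130 to 171. DESeq2 made 24 to 55 false calls there. For differences among lines, 38% of 2-fold and 86% of 4-fold changes were recovered.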

Results

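Gene expression was measured by RNA sequencing in BxPC-3, MIA PaCa-2 and PANC-1, established lines of human pancreatic ductal adenocarcinoma, after 48 h with DMSO, GW3965, 1E5 or 3A4 at 10 µM. Each of the 12 groups held 3 libraries. Totals ran from 19605935 to 25888304 counts per library in BxPC-3 and from 14960970 to 26026684 in PANC-1. They were less even in MIA PaCa-2, with 3609582 to 10996848 counts in the DMSO libraries, 2701393 to 13631719 with GW3965, 8889927 to 24588097 with 3A4 and 23675670 to 25503827 with 1E5. The median SE of a log2 fold change against DMSO was 0.204 in BxPC-3, 0.263 to 0.269 in MIA PaCa-2 and 0.24 to 0.242 in PANC-1. Genes encoded by mitochondrial DNA took 7.54% ± 0.0321 (SD, n = 3) of the counts of MIA PaCa-2 with DMSO and 2.04% ± 0.722 with 1E5. In PANC-1 they took 6.82% ± 0.707 with DMSO and 4.40% ± 2.00 with 1E5, with 6.59% in 1E5 replicate 2, and in BxPC-3 the group means lay between 7.62% and 8.50%. No pair of replicates was within sampling noise, since the chi-square per degree of freedom ran from 8.62 to 155 over the 36 pairs.

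**Figure D1:**
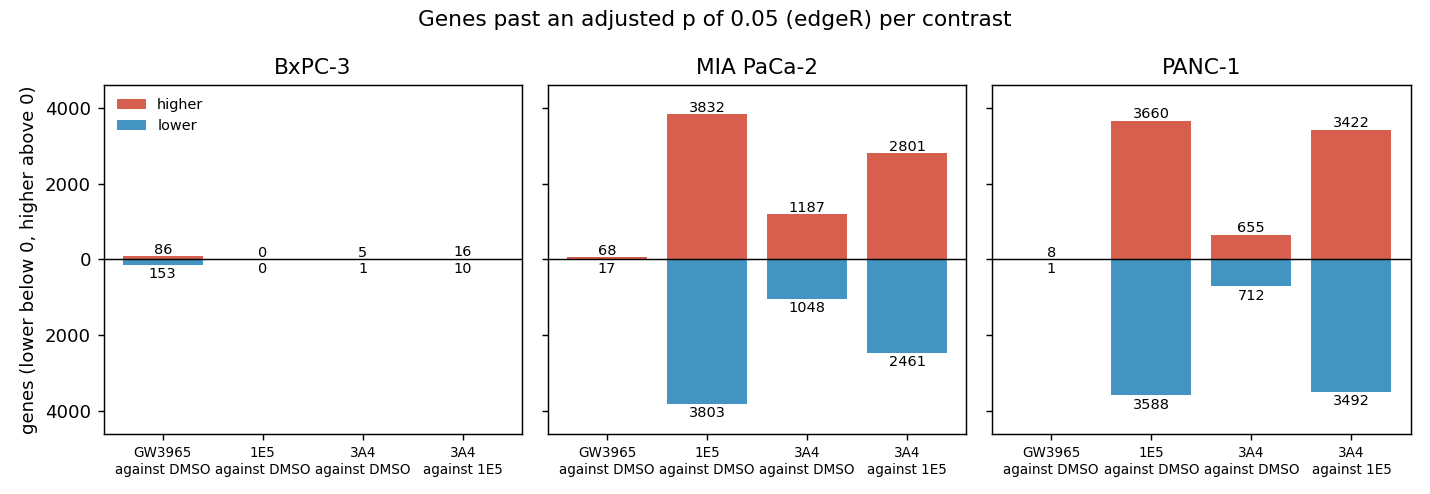
Number of genes higher (upwards) and lower (downwards) at an edgeR adjusted p below 0.05, for each ligand against DMSO and for 3A4 against 1E5, in each line with 3 libraries per group. 1E5 has the highest bars in MIA PaCa-2 (3832 higher, 3803 lower) and PANC-1 (3660 higher, 3588 lower) and none in BxPC-3.

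GW3965 was compared with DMSO in each line to find the genes that respond to an LXR agonist. ABCA1 (ENSG00000165029; GRCh38, chromosome 9, 104781002 to 104928237), which exports cellular cholesterol, rose in every line. Its level went from 44.9 ± 11.6 to 337 ± 15.9 CPM in BxPC-3 (7.5-fold; edgeR adjusted p = 0.00306), from 13.5 ± 3.95 CPM by 7.45-fold in MIA PaCa-2 (log2 2.90 ± 0.337; adjusted p = 0.0038) and from 7.35 ± 1.58 to 190 ± 43.7 CPM in PANC-1 (25.8-fold; adjusted p = 1.74e-05). Of the 14517 genes tested in all lines it was the only 1 called higher in all of them, where independent lists would give 0.000183. ABCG1 (ENSG00000160179; chromosome 21, 42199689 to 42297244), a related sterol exporter, rose 8.15-fold in MIA PaCa-2 (log2 3.03 ± 0.403 SE) and 35.6-fold in PANC-1 (log2 5.15 ± 0.294). In BxPC-3 it was at 8.85 ± 3.78 CPM against 9.05 ± 2.76 with DMSO, a log2 fold change of -0.03 ± 0.357 (adjusted p = 0.988), and this response differed among the lines (interaction test in edgeR, adjusted p = 2.9e-05). That of ABCA1 did not pass the same test (adjusted p = 0.128). The ABCG1 call in MIA PaCa-2 ended without DMSO replicate 2 (adjusted p = 0.0547).

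Of the 15 LXR targets measured, 7 rose with GW3965 in BxPC-3, 5 in MIA PaCa-2 and 4 in PANC-1, and none fell. The counts adjusted over the list alone were 7, 7 and 9 higher, with 1 lower in PANC-1. FASN (ENSG00000169710; chromosome 17, 82078333 to 82098332), the synthase of palmitate, rose 2.92-fold in BxPC-3 and 2.41-fold in MIA PaCa-2. SCD (ENSG00000099194; chromosome 10, 100347124 to 100364834), the desaturase that makes oleate, rose 3.00-fold in MIA PaCa-2, to 4690 ± 1040 CPM, and 3.71-fold in BxPC-3. MYLIP (ENSG00000007944; chromosome 6, 16129125 to 16148248), a ligase that marks the LDL receptor for degradation, rose 3.55-fold in PANC-1 (log2 1.83 ± 0.112) and 2.16-fold in BxPC-3. SREBF1 (ENSG00000072310; chromosome 17, 17810399 to 17837002), a regulator of lipogenic genes, rose 2.98-fold in BxPC-3 and 1.71-fold in MIA PaCa-2. In PANC-1 the levels of SREBF1 (521 ± 53.3 against 197 ± 54.8 CPM), SCD (22500 ± 2330 against 8240 ± 2860 CPM) and FASN (2970 ± 116 against 1460 ± 21.3 CPM) had edgeR adjusted p-values of 0.637, 1 and 0.332. For each of these genes every GW3965 library lay above every DMSO library, so the p-values do not show an absence of response. The spread in the test was shared with the 1E5 libraries, of which replicate 2 stood apart for SCD (3298 CPM against 529.1 and 594). Replicate 2 was also the highest for SCD in both compared groups. It was at 11540 CPM with DMSO (6548 and 6645 in replicates 1 and 3) and 25040 with GW3965 (21900 and 20480). Camera placed the list higher in BxPC-3 (adjusted p = 1.3e-07; adjusted p = 0.2 with an estimated correlation), MIA PaCa-2 (1.88e-10; adjusted p = 0.0835 with an estimated correlation) and PANC-1 (1.59e-19; adjusted p = 0.0482 with an estimated correlation). In BxPC-3 the calls of SCD and MYLIP ended without any 1 of the 6 libraries (highest adjusted p = 0.121 and 0.113) and that of SREBF1 without DMSO replicate 1 (0.0685). In MIA PaCa-2 SREBF1 kept its call only without GW3965 replicate 3 (highest 0.0961), and it also lost it with only the compared groups and without the 2 shallowest libraries. With all 36 libraries in 1 fit that call and those of SCD in BxPC-3 and MIA PaCa-2 ended.

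**Figure D2:**
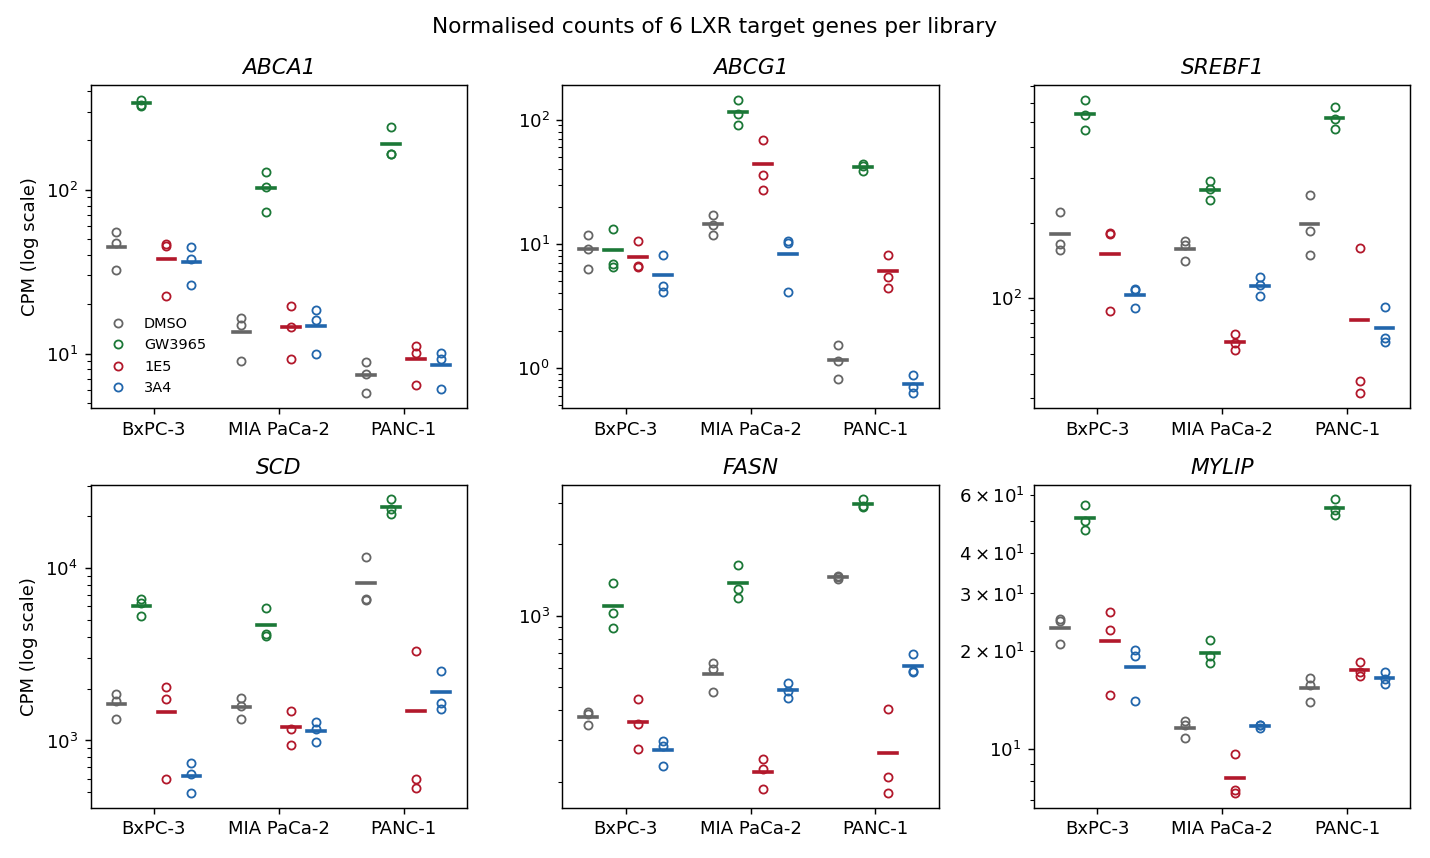
Level of each plotted LXR target in CPM on a log axis, by line and ligand, with 1 point per library and a bar at the mean of 3 libraries. ABCA1 with GW3965 sits at 337 CPM in BxPC-3 and 190 CPM in PANC-1, above every library of the other groups of its line.

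In BxPC-3, 239 genes changed with GW3965 (86 higher and 153 lower, 122 of them by at least 2-fold). Interferon response genes made up the list with the most members called, since 17 of 20 fell and 3 did not pass (20 adjusted over the list alone), with a median log2 fold change of -1.50. IFIT1, which binds viral RNA, fell 5.85-fold from 270 ± 99.3 to 46.0 ± 19.0 CPM, ISG15, a ubiquitin-like modifier, 3.33-fold, and USP18, which removes it, 6.08-fold (edgeR adjusted p = 0.00475, 0.00306 and 0.00355). Camera gave this list an adjusted p of 2.56e-30 (adjusted p = 0.109 with an estimated correlation). Of 16 fatty acid synthesis genes 6 rose (10 adjusted over the list alone), among them ME1, which makes NADPH, by 1.64-fold (camera adjusted p = 1.38e-09; adjusted p = 0.109 with an estimated correlation). Of 11 PPAR targets and lipid droplet genes 4 rose (5 adjusted over the list alone), such as PLIN2, a droplet coat protein, from 28.2 ± 6.07 to 66.2 ± 2.18 CPM (camera adjusted p = 1.73e-08; adjusted p = 0.0478 with an estimated correlation). The mucosal gene SPINK4 fell 5.68-fold. The number of genes changed depended on single libraries: it was 68 without DMSO replicate 1, 90 without DMSO replicate 2, 151 without DMSO replicate 3, 124 without GW3965 replicate 1, 112 without replicate 2 and 84 without replicate 3. It was 110 with all 36 libraries in 1 fit, 90 with only the compared groups, 478 with the replicate block and 599 with DESeq2.

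Of 22 integrated stress response genes 5 rose with GW3965 in BxPC-3 (16 adjusted over the list alone), which gave a camera adjusted p of 5.08e-14 (adjusted p = 0.109 with an estimated correlation). Its members ASNS, asparagine synthetase (3.04-fold), and TRIB3 (2.48-fold) kept their calls only without GW3965 replicate 3 among the fits that left out 1 library (highest adjusted p = 0.0893 and 0.0823). NRF2 targets (2 of 16 higher, 5 adjusted over the list alone) and ribosomal protein genes (1 of 20 higher, 6 adjusted over the list alone) had camera adjusted p-values of 7.19e-05 and 1.02e-08 (adjusted p = 0.203 and 0.333 with an estimated correlation). DNA replication and ER chaperone genes had no member past the threshold over all genes, and 9 of 25 and 4 of 15 were lower adjusted over the list alone (camera adjusted p = 1.96e-09 and 0.00136; adjusted p = 0.345 and 0.144 with an estimated correlation). Immediate early genes were lower (1 of 14, 3 adjusted over the list alone) and mitochondrially encoded genes higher (0 of 13, 0 adjusted over the list alone), with camera adjusted p-values of 0.0143 and 0.00448 (adjusted p = 0.141 and 0.437 with an estimated correlation). Both of these calls also ended with all 36 libraries in 1 fit.

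In MIA PaCa-2, 85 genes changed with GW3965, 68 of them higher. Integrated stress response genes led these, with 17 of 21 higher, 4 that did not pass and 21 higher adjusted over the list alone (median log2 fold change 1.43; camera adjusted p = 8.3e-34; adjusted p = 0.0482 with an estimated correlation). ASNS rose 3.33-fold from 66.9 ± 12.7 to 223 ± 61.0 CPM, and the transcription factors ATF4 and CEBPG rose 2.47-fold and 2.22-fold (edgeR adjusted p = 0.0038, 0.00235 and 0.0038). Of 16 fatty acid synthesis genes 5 rose (9 adjusted over the list alone; camera adjusted p = 3.35e-09; adjusted p = 0.0877 with an estimated correlation), of 22 cholesterol synthesis and uptake genes 2 (13 adjusted over the list alone; 7.8e-09; adjusted p = 0.0478 with an estimated correlation) and of 15 NRF2 targets 1 (5 adjusted over the list alone; 1.67e-05; adjusted p = 0.0478 with an estimated correlation). Of 12 NF-kB and chemokine genes 1 rose (3 adjusted over the list alone; 0.000953; adjusted p = 0.292 with an estimated correlation). Lower as groups, with no member past the threshold over all genes, were DNA replication (5 of 25 lower adjusted over the list alone), mitosis (0 of 23) and mitochondrially encoded genes (0 of 13), with camera adjusted p-values of 3.36e-09, 6.89e-06 and 0.00262 (adjusted p = 0.292, 0.317 and 0.579 with an estimated correlation). KLF9, a transcription factor induced by steroid hormones, fell 3.95-fold from 21.2 ± 1.47 to 5.39 ± 0.205 CPM. S100P, a calcium-binding protein of pancreatic tumours, had no count in the 3 DMSO libraries and 5.39 ± 1.71 CPM with GW3965, at least 36-fold higher, but its call ended without DMSO replicate 1 or 2 or GW3965 replicate 1 (highest adjusted p = 0.0863). It also ended with limma-voom, with only the compared groups, without the 2 shallowest libraries and without the 1E5 libraries. The count of 85 fell to 32 without DMSO replicate 1, 16 without DMSO replicate 2, 29 without DMSO replicate 3, 24 without GW3965 replicate 1 and 36 without GW3965 replicate 2, in a line whose DMSO and GW3965 libraries were the shallowest. It was 192 with all 36 libraries in 1 fit, 264 with DESeq2, 18 with limma-voom, 22 with only the compared groups and, in a fit added after the data were seen, 41 without the 1E5 libraries.

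In PANC-1, 9 genes changed with GW3965. ABCA1, ABCG1 and MYLIP rose as given above, together with S100P (4.19-fold), ME1 (2.24-fold), the citrate lyase gene ACLY (1.72-fold) and FDPS of the mevalonate pathway (1.70-fold), and TMEM263 fell 2.69-fold from 55.4 ± 15 to 20.6 ± 4.33 CPM. The ninth gene, LPCAT3, an acyltransferase of phospholipids that falls outside the naming rule and was chosen after its values were seen, rose from 58.1 to 157 CPM (log2 1.43 ± 0.0997; edgeR adjusted p = 4.92e-05). Of 16 fatty acid synthesis genes 2 rose (12 adjusted over the list alone; camera adjusted p = 1.07e-21; adjusted p = 0.0478 with an estimated correlation). None of 22 integrated stress response genes passed over all genes and 17 were higher adjusted over the list alone (camera adjusted p = 4.16e-22; adjusted p = 0.0877 with an estimated correlation), and of 14 NRF2 targets 1 rose (7 adjusted over the list alone; 1.58e-11; adjusted p = 0.0877 with an estimated correlation). Of 23 cholesterol synthesis and uptake genes 1 rose (2 adjusted over the list alone), and of 10 PPAR targets and lipid droplet genes none (3 higher and 1 lower adjusted over the list alone), with camera adjusted p-values of 2.18e-06 and 0.00437 (adjusted p = 0.375 and 0.109 with an estimated correlation). The count of 9 was 4 without GW3965 replicate 1 and 35 without DMSO replicate 2. It was 19 with all 36 libraries in 1 fit, 99 with DESeq2 and, in a fit added after the data were seen, 15 without the 1E5 libraries. Without 1 library the calls of S100P, ME1, ACLY, FDPS and TMEM263 reached adjusted p-values of 0.119, 0.0674, 0.253, 0.253 and 0.253. Both ME1 and TMEM263 lost theirs without GW3965 replicate 1 or DMSO replicate 3, TMEM263 also without GW3965 replicate 3, S100P without DMSO replicate 1 or 3 or GW3965 replicate 1 or 2, ACLY without any library but DMSO replicate 2, and FDPS without any of the 6. With only the compared groups the calls of S100P, TMEM263, ACLY and FDPS ended, with RLE scaling those of ACLY and FDPS, with no filter that of FDPS and with all 36 libraries in 1 fit that of TMEM263. That of S100P also ended with limma-voom, those of S100P and FDPS after thinning, and those of S100P and TMEM263 without the 1E5 libraries.

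1E5 was compared with DMSO to find the genes that respond to it alone. In MIA PaCa-2, 7635 of 16254 genes changed (3832 higher and 3803 lower, 4617 by at least 2-fold). All 23 mitosis genes fell, with a median log2 fold change of -1.64, and 22 of 25 DNA replication genes fell (23 adjusted over the list alone), with a median of -2.13. KIF20A, a kinesin of cytokinesis, fell 14.7-fold from 171 ± 32.6 to 11.6 ± 2.09 CPM, AURKB, a mitotic kinase, 8.50-fold, CDC45, a part of the replicative helicase, 10.2-fold and TK1, thymidine kinase, 8.84-fold (edgeR adjusted p = 1.15e-07, 1.36e-07, 3.48e-07 and 4.59e-07). All 13 mitochondrially encoded genes fell (median -2.44), MT-CO2 from 11400 ± 893 to 888 ± 477 CPM. Camera gave these lists adjusted p-values of 2.89e-13, 3.58e-13 and 2.61e-09 (adjusted p = 0.135, 0.2 and 0.286 with an estimated correlation). Of 22 cholesterol synthesis and uptake genes 16 fell and 2 rose, also adjusted over the list alone, with LSS, lanosterol synthase, 3.24-fold lower (camera adjusted p = 7.63e-05; adjusted p = 0.057 with an estimated correlation).

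Of 21 integrated stress response genes 19 rose with 1E5 in MIA PaCa-2 (21 adjusted over the list alone; median log2 fold change 2.56; camera adjusted p = 1.29e-11; adjusted p = 0.188 with an estimated correlation). Of 15 NRF2 targets 12 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.0478 with an estimated correlation). HMOX1, which breaks down heme, rose 14.6-fold from 23.4 ± 7.29 to 335 ± 35.8 CPM, PPP1R15A, a phosphatase subunit of the stress response, 7.86-fold and GCLC of glutathione synthesis 5.35-fold. Of 13 p53 targets 10 rose (11 adjusted over the list alone), such as the cell cycle inhibitor CDKN1A by 15.8-fold (log2 3.98 ± 0.315). Of 12 NF-kB and chemokine genes 9 rose and 1 fell, such as CXCL8 by 5.5-fold, and of 14 immediate early genes 9 rose, such as JUNB by 4.44-fold, with the same counts for both adjusted over the list alone. Their camera adjusted p-values were 0.000738, 0.00303 and 0.0143 (adjusted p = 0.271, 0.327 and 0.324 with an estimated correlation). LCN2, a siderophore-binding protein, and LAMP3, a lysosomal membrane protein, had no count in the 3 DMSO libraries and 52.9 ± 5.08 and 32.7 ± 3.65 CPM with 1E5, at least 355-fold and 219-fold higher. Of 6 genes in the list of other cell types 4 fell, also adjusted over the list alone: the collagen genes COL1A2 (16.0-fold) and COL3A1 (outside the naming rule and chosen after its values were seen), the monocyte receptor CD14 (63.2-fold) and the endothelial cadherin CDH5 (113-fold, from 23.7 ± 2.08 to 0.204 ± 0.353 CPM), with a camera adjusted p of 0.00628 (adjusted p = 0.2 with an estimated correlation). Without 1E5 replicate 3 COL1A2 was at log2 -4.70, without replicates 1 and 2 CD14 was at -5.39 and -6.58, and all counts of CDH5 with 1E5 came from replicate 3.

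Among LXR targets in MIA PaCa-2, ABCG1 rose with 1E5 (44.0 ± 21.7 against 14.3 ± 2.68 CPM; log2 1.62 ± 0.387; edgeR adjusted p = 0.00419). SREBF1 fell from 158 ± 14.8 to 67.0 ± 4.81 CPM (log2 -1.24 ± 0.128) and FASN from 569 ± 80.4 to 221 ± 32.5 CPM (log2 -1.37 ± 0.164). ABCA1 was at 14.4 ± 5.07 against 13.5 ± 3.95 CPM (adjusted p = 0.885) and SCD at 1200 ± 273 against 1560 ± 214 CPM (adjusted p = 0.127). In all, 2 of 15 rose and 5 fell (3 and 5 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.14). By fry it was lower (adjusted p = 0.00746). That test does not set a list against the other genes, and 47% of all genes tested were called in this contrast. It therefore does not set the LXR targets apart. MYLIP fell 1.42-fold, a call kept only without 1E5 replicate 3 (highest adjusted p = 0.125 without 1 library). It also ended with RLE scaling, no filter, all 36 libraries in 1 fit, DESeq2 or only the compared groups, after thinning and without the 2 shallowest libraries. NR1H2, which encodes LXR beta, rose 1.48-fold (adjusted p = 0.00853).

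In PANC-1, 7248 of 18544 genes changed with 1E5 (3660 higher and 3588 lower, 3496 by at least 2-fold). All 23 mitosis genes fell (median log2 fold change -2.02), as did 23 of 25 DNA replication genes (median -1.78) and 11 of 13 mitochondrially encoded genes (median -1.35), with the same counts adjusted over the lists alone. KIF11, a spindle kinesin, fell 5.78-fold from 128 ± 18.9 to 22.1 ± 2.21 CPM, MCM10, a replication initiation factor, 9.71-fold and MT-CYB 4.58-fold. Camera gave adjusted p-values of 2.39e-11, 2.62e-11 and 3.52e-07 (adjusted p = 0.333, 0.327 and 0.343 with an estimated correlation). Of 23 cholesterol synthesis and uptake genes 17 fell and of 16 fatty acid synthesis genes 12 fell and 2 rose, also adjusted over the lists alone. LSS fell 5.09-fold, FADS2, a desaturase of polyunsaturated fatty acids, 12.7-fold from 798 ± 154 to 63.0 ± 20.5 CPM, and ACACA, acetyl-CoA carboxylase, 3.31-fold (camera adjusted p = 4.64e-08 and 0.000966 for the lists; adjusted p = 0.327 and 0.321 with an estimated correlation).

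Of 22 integrated stress response genes 21 rose and 1 fell with 1E5 in PANC-1, also adjusted over the list alone (camera adjusted p = 2.19e-10; adjusted p = 0.2 with an estimated correlation), and of 14 NRF2 targets 12 rose (14 adjusted over the list alone; 8.69e-08; adjusted p = 0.141 with an estimated correlation). HMOX1 rose 12.9-fold from 118 ± 9.11 to 1530 ± 326 CPM and OSGIN1, an oxidative stress gene, 8.11-fold. HSPA5, the main ER chaperone, rose 11.7-fold from 792 ± 37.2 to 9240 ± 2550 CPM. Of 15 ER chaperones 8 rose, also adjusted over the list alone, but the camera call (adjusted p = 0.0215; adjusted p = 0.605 with an estimated correlation) ended without 1E5 replicate 2 (adjusted p = 0.272). Of 20 ribosomal protein genes 17 rose (18 adjusted over the list alone), RPS18 by 2.09-fold (camera adjusted p = 3.95e-06; adjusted p = 0.489 with an estimated correlation). LCN2, at 12.2 ± 6.17 CPM, the zinc transporter SLC30A2, at 20.8 ± 13.7 CPM, and the xenobiotic-metabolising CYP1A1, at 7.18 ± 3.29 CPM, had no count in DMSO and were so at least 286-fold, 490-fold and 169-fold higher, and the protocadherin PCDH20 was at least 317-fold lower, from 13.0 ± 2.71 CPM. These folds use group means, and the counts of SLC30A2 with 1E5 ran from 148 to 851. Of 8 markers of the classical subtype of pancreatic tumours 4 fell, also adjusted over the list alone, with AGR2 17.9-fold lower, but the camera call (adjusted p = 0.0257; adjusted p = 0.188 with an estimated correlation) ended without 1E5 replicate 2 (adjusted p = 0.0664) and with all 36 libraries in 1 fit.

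Of the 15 LXR targets in PANC-1, 5 rose and 6 fell with 1E5, also adjusted over the list alone. The list did not pass (camera adjusted p = 0.778, fry adjusted p = 0.116; median 0.181, mean -0.0543). ABCG1 rose 5.13-fold from 1.16 ± 0.364 to 5.99 ± 1.95 CPM (log2 2.36 ± 0.274; edgeR adjusted p = 6.37e-05), while ABCA1 was at 9.23 ± 2.48 against 7.35 ± 1.58 CPM (adjusted p = 0.349). FASN fell 5.52-fold from 1460 ± 21.3 to 264 ± 121 CPM and SCD 5.59-fold from 8240 ± 2860 to 1470 ± 1580 CPM. The 1E5 libraries of SCD held 529.1, 3298 and 594 CPM, and without 1E5 replicate 2 its log2 fold change of -2.48 ± 0.603 was -3.87 and that of SREBF1 -2.14. The call of SREBF1 (log2 -1.26 ± 0.423; adjusted p = 0.0341) ended without 1E5 replicate 1 or 3 or DMSO replicate 2 or 3 (highest adjusted p = 0.107) and with only the compared groups. The receptor genes NR1H2 (1.47-fold) and NR1H3, which encodes LXR alpha (1.85-fold), rose.

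In BxPC-3 no gene passed with 1E5 in edgeR, while 572 of 18042 had an unadjusted p below 0.05. DESeq2 called 12 genes and limma-voom 0, and edgeR called 4 without 1E5 replicate 2 and 1 with only the compared groups. ABCA1 was at 38.0 ± 13.5 against 44.9 ± 11.6 CPM, ABCG1 at 7.85 ± 2.28 against 9.05 ± 2.76 and SCD at 1460 ± 762 against 1630 ± 268, each with an adjusted p of 1, as had FASN, SREBF1 and MYLIP. Interferon response genes were lower as a group, with 0 of 20 past the threshold and 0 adjusted over the list alone (median log2 fold change -0.40; camera adjusted p = 8.74e-10; adjusted p = 0.324 with an estimated correlation). Of 10 AHR and xenobiotic targets 2 were higher adjusted over the list alone, CYP1A1 and CYP1B1, enzymes of xenobiotic oxidation (camera adjusted p = 0.00409; adjusted p = 0.109 with an estimated correlation). Both lie outside the naming rule here and were chosen after their values were seen, and CYP1A1 had a log2 fold change of 2.31 ± 0.677. Immediate early genes were lower as a group (0 of 14, 0 adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.0877 with an estimated correlation).

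3A4 was compared with DMSO in the same way. In MIA PaCa-2, 2235 genes changed (1187 higher and 1048 lower, 967 by at least 2-fold). Of 12 NF-kB and chemokine genes 9 rose (11 adjusted over the list alone), CXCL8 6.37-fold from 44.7 ± 9.42 to 285 ± 89.8 CPM, the apoptosis inhibitor BIRC3 5.26-fold and IL1B 5.28-fold (edgeR adjusted p = 0.000222, 0.000222 and 0.00054). Of 21 integrated stress response genes 13 rose (16 adjusted over the list alone), ATF3 by 6.85-fold, and of 14 immediate early genes 6 rose (8 adjusted over the list alone), EGR1 by 3.50-fold. Camera gave these lists adjusted p-values of 9.23e-09, 6.52e-09 and 8.99e-05 (adjusted p = 0.109, 0.231 and 0.144 with an estimated correlation). Of 23 mitosis genes 8 rose, also adjusted over the list alone, CDC20 by 1.67-fold (camera adjusted p = 0.00105; adjusted p = 0.426 with an estimated correlation), and of 5 histone genes 3 (4 adjusted over the list alone), H2BC4 by 6.09-fold (0.0031; adjusted p = 0.327 with an estimated correlation). Of 9 mesenchymal genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0171; adjusted p = 0.214 with an estimated correlation). The count of genes was 1203 without DMSO replicate 1, 1167 without DMSO replicate 2, 830 without DMSO replicate 3 and 749 without 3A4 replicate 2. It was 3820 with all 36 libraries in 1 fit and, in a fit added after the data were seen, 1085 without the 2 shallowest libraries. The near even split depended on the fit, with 2638 higher and 1182 lower with all 36 libraries, 1251 and 627 with no filter, and 1095 and 1256 with limma-voom.

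Fewer lists fell with 3A4 in MIA PaCa-2. Of 18 interferon response genes 6 fell (7 adjusted over the list alone), IFIT1 from 73.4 ± 7.51 to 25.9 ± 6.61 CPM and BST2, which tethers virions, 5.99-fold (camera adjusted p = 0.000299; adjusted p = 0.124 with an estimated correlation). Of 20 ribosomal protein genes 7 fell (14 adjusted over the list alone), RPL3 by 2.37-fold (1.33e-06; adjusted p = 0.375 with an estimated correlation). Of 15 NRF2 targets 8 rose and 2 fell (9 and 2 adjusted over the list alone), AKR1C1 rising 3.16-fold and NQO1 falling 2.30-fold (0.00163; adjusted p = 0.0877 with an estimated correlation). Of 15 LXR targets 2 fell, also adjusted over the list alone, LPCAT3 2.03-fold and SREBF1 1.41-fold, and the list's call (camera adjusted p = 0.0353; adjusted p = 0.423 with an estimated correlation) ended without 3A4 replicate 1 or DMSO replicate 1 (highest 0.0754) and with all 36 libraries in 1 fit. The call of SREBF1 itself ended without DMSO replicate 1 or 2 or 3A4 replicate 2 or 3 (highest edgeR adjusted p = 0.0921), and with no filter, all 36 libraries in 1 fit or only the compared groups. ABCA1 was at 14.8 ± 4.38 against 13.5 ± 3.95 CPM (adjusted p = 0.843) and ABCG1 at 8.24 ± 3.58 against 14.3 ± 2.68 CPM (adjusted p = 0.188), and SCD, FASN and MYLIP had adjusted p-values of 0.14, 0.358 and 0.959. NEURL3, a ubiquitin ligase, had no count with DMSO and 7.20 ± 1.05 CPM with 3A4, at least 48-fold higher.

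In PANC-1, 1367 genes changed with 3A4 (655 higher and 712 lower, 479 by at least 2-fold). Of 16 fatty acid synthesis genes 5 fell (10 adjusted over the list alone), FADS2 3.35-fold from 798 ± 154 to 238 ± 61.8 CPM and ACLY 1.74-fold. Of 23 cholesterol synthesis and uptake genes 3 fell (7 adjusted over the list alone), TM7SF2 by 3.27-fold and LSS by 2.12-fold, and of 15 LXR targets 4 fell (6 adjusted over the list alone), LPCAT3 by 1.59-fold. Camera gave adjusted p-values of 4.97e-06, 4.68e-06 and 0.00705 (adjusted p = 0.2, 0.401 and 0.414 with an estimated correlation). FASN fell 2.36-fold from 1460 ± 21.3 to 617 ± 64 CPM (edgeR adjusted p = 0.0122), a call that ended without 3A4 replicate 1 or 3 (highest 0.0592). SCD was at 1900 ± 539 against 8240 ± 2860 CPM (edgeR adjusted p = 0.0533), SREBF1 at 76.3 ± 13.9 against 197 ± 54.8 (0.0738) and ABCA1 at 8.49 ± 2.11 against 7.35 ± 1.58 (0.687), and ABCG1 and MYLIP had adjusted p-values of 0.22 and 0.629. Of 13 immediate early genes 5 rose (8 higher and 1 lower adjusted over the list alone), EGR1 by 8.83-fold, and of 13 NF-kB and chemokine genes 4 (9 adjusted over the list alone), BIRC3 by 2.04-fold. Of 6 markers of the basal-like tumour subtype 3 rose, also adjusted over the list alone, with the growth factor AREG at 3.42-fold, S100A2 at 3.62-fold and DHRS9. For these lists the camera adjusted p-values were 0.000327, 3.3e-06 and 0.0255 (adjusted p = 0.135, 0.141 and 0.188 with an estimated correlation). The kinase gene CAMK2A rose 17.0-fold to 7.43 ± 1.09 CPM and SPDEF, an epithelial transcription factor, fell 16.4-fold from 4.25 ± 0.941 CPM. The count of genes was 429 without 3A4 replicate 1, 737 without replicate 2, 495 without replicate 3, 532 without DMSO replicate 2 and 611 without DMSO replicate 3. It was 2564 with DESeq2, 2403 with only the compared groups, 903 with no filter on low counts and, in a fit added after the data were seen, 3020 without the 1E5 libraries, a fit in which the basal-like list did not pass. The call of DHRS9 ended without 3A4 replicate 1 or 3 or DMSO replicate 2 or 3 (highest 0.0811).

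In BxPC-3, 6 genes changed with 3A4, and 2292 had an unadjusted p below 0.05. The linker histone gene H1-2 (2.72-fold, to 53 ± 5.74 CPM), NAV2 (2.68-fold), LCN2 (2.04-fold) and UPP1, uridine phosphorylase (2.01-fold), rose, and SLITRK6 fell 2.11-fold. The sixth, ENSG00000282034, has no symbol in the table, falls outside the naming rule and was chosen after its values were seen (41.8 to 110 CPM; edgeR adjusted p = 0.0235). H1-2 and NAV2 lost their calls without any of the 6 libraries but 3A4 replicate 3 (highest adjusted p = 0.133 and 0.16), LCN2 and UPP1 without any of them (0.213 for both) and SLITRK6 without 3A4 replicate 1 or DMSO replicate 1 or 2 (0.118). With all 36 libraries in 1 fit LCN2 and SLITRK6 lost theirs, and with only the compared groups LCN2 and NAV2. The count was 0 without DMSO replicate 1 or 2 and 3 without DMSO replicate 3. It was 11 with all 36 libraries in 1 fit, 14 with limma-voom, 275 with the replicate number as a block and 365 with DESeq2. Among lists with no member past the threshold over all genes, cholesterol synthesis and uptake (13 of 24 lower adjusted over the list alone), fatty acid synthesis (9 of 16 lower and 1 higher) and LXR targets (2 of 15 lower) were lower as groups. Camera adjusted p-values were 1.07e-09, 0.00015 and 0.00261 (adjusted p = 0.231, 0.259 and 0.414 with an estimated correlation). Of 17 NF-kB and chemokine genes 7 were higher, and of 20 interferon response genes 12 lower, adjusted over the list alone (camera adjusted p = 8.49e-07 and 1.73e-08; adjusted p = 0.25 and 0.345 with an estimated correlation). Immediate early genes (4 of 14 adjusted over the list alone) and histone genes (1 of 5 higher, 3 adjusted over the list alone) were higher (0.0114 and 0.0052; adjusted p = 0.14 and 0.292 with an estimated correlation), the former not with all 36 libraries in 1 fit. SCD was at 624 ± 123 against 1630 ± 268 CPM (edgeR adjusted p = 0.179), and SREBF1, FASN, MYLIP, ABCG1 and ABCA1 had adjusted p-values of 0.234, 0.346, 0.443, 0.467 and 0.689.

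3A4 and 1E5 were then compared with each other at the same dose and time. In MIA PaCa-2, 5262 genes differed (2801 higher and 2461 lower with 3A4; 2293 and 1579 without 3A4 replicate 1). All 23 mitosis, 23 of 25 DNA replication and all 13 mitochondrially encoded genes were higher with 3A4, and 20 of 21 integrated stress response genes and 10 of 13 p53 targets were lower. LCN2 was 386-fold lower with 3A4 (0.0949 ± 0.164 against 52.9 ± 5.08 CPM; edgeR adjusted p = 7.33e-05), with all its counts in 3A4 replicate 2. ALOX5AP, of leukotriene synthesis, had no count with 3A4 against 44.5 ± 13.7 CPM, at least 778-fold lower. Among LXR targets, ABCG1 was lower with 3A4 by log2 -2.44 ± 0.389 (adjusted p = 0.000462), and FASN (1.14 ± 0.162), SREBF1 (0.74 ± 0.127) and MYLIP (0.53 ± 0.18) were higher. The difference was not past the threshold for ABCA1 (0.05, 95% interval -0.619 to 0.723) or SCD (-0.07, -0.494 to 0.357). Of the 15 LXR targets 5 were higher and 2 lower (5 and 3 adjusted over the list alone).

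In PANC-1, 6914 genes differed between 3A4 and 1E5 (3422 higher and 3492 lower with 3A4). Again all 23 mitosis genes, 24 of 25 DNA replication genes and 11 of 13 mitochondrially encoded genes were higher with 3A4, and 21 of 22 integrated stress response genes, 12 of 14 NRF2 targets and 16 of 20 ribosomal protein genes were lower. FAM111B, a protease gene, was 47.5-fold higher with 3A4 (40.6 ± 1.64 against 0.843 ± 0.334 CPM; edgeR adjusted p = 1.13e-06), and ALDH1L1, of folate metabolism, had no count with 3A4 and was at least 123-fold lower. ABCG1 was lower with 3A4 by log2 -3.01 ± 0.29 (adjusted p = 2.15e-05) and FASN higher by 1.23 ± 0.24 (adjusted p = 0.00208). The difference was not past the threshold for ABCA1 (-0.13, 95% interval -0.696 to 0.444), SREBF1 (-0.11, -1.02 to 0.807), SCD (0.37, -0.883 to 1.62) or MYLIP (-0.08, -0.322 to 0.158). Of the 15 LXR targets 3 were higher and 4 lower with 3A4, also adjusted over the list alone.

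In BxPC-3, 26 genes differed between 3A4 and 1E5 (16 higher and 10 lower with 3A4). H1-2 was 3.02-fold higher with 3A4 (53 ± 5.74 against 17.6 ± 3.16 CPM), TRAF1, an adaptor of TNF receptors, 3.69-fold higher, the imprinted RNA gene H19 8.91-fold lower and the keratin KRT4 3.15-fold lower (edgeR adjusted p = 0.023, 0.0308, 0.0274 and 0.039). None of 15 LXR targets differed, by either adjustment. The log2 differences were -0.07 for ABCA1 (95% interval -0.678 to 0.54), -0.49 for ABCG1 (-1.27 to 0.304), -0.55 for SREBF1 (-1.07 to -0.0225), -0.40 for FASN (-0.809 to 0.0156), -0.26 for MYLIP (-0.703 to 0.18) and -1.23 for SCD (-1.98 to -0.481), intervals that are not adjusted for the number of genes. The count was 6 without 3A4 replicate 1, 9 without 3A4 replicate 2, 7 without 3A4 replicate 3, 7 without 1E5 replicate 2 and 0 without 1E5 replicate 3. It was 9 with all 36 libraries in 1 fit, 9 with only the compared groups, 412 with the replicate block and 486 with DESeq2. H1-2 lost its call without 1E5 replicate 3 (0.0676), TRAF1 also without 1E5 replicate 2 or 3A4 replicate 1 or 2 (highest 0.162), and H19 and KRT4 without any library but 1E5 replicate 1 (highest 0.117 and 0.187). With only the compared groups TRAF1 and KRT4 lost theirs, and KRT4 also with all 36 libraries in 1 fit.

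The inverse agonists were also set against the agonist. Of 15 LXR targets, 1E5 was lower than GW3965 for 7 in BxPC-3, 10 in MIA PaCa-2 and 9 in PANC-1, and 3A4 for 8, 9 and 9 with none higher. SMPDL3A in MIA PaCa-2 and, in PANC-1, the phospholipid transfer gene PLTP and the lipogenic regulator MLXIPL were higher with 1E5, genes outside the naming rule that were chosen after their values were seen. Adjusted over the list alone the lower counts were 8, 10 and 9 for 1E5 and 8, 11 and 9 for 3A4. ABCA1 was 8.87-fold, 7.11-fold and 20.5-fold lower with 1E5 than with GW3965 in BxPC-3, MIA PaCa-2 and PANC-1, and 9.30-fold, 6.86-fold and 22.4-fold lower with 3A4 (edgeR adjusted p from 1.84e-06 to 0.00401). ABCG1 was 2.64-fold lower with 1E5 and 14.3-fold lower with 3A4 in MIA PaCa-2, and in BxPC-3 its log2 differences were -0.17 ± 0.358 and -0.66 ± 0.362 (adjusted p = 0.911 and 0.294). The median log2 difference of the 15 genes ran from -0.65 (1E5 in BxPC-3) to -1.52 (1E5 in PANC-1). For 1E5 in BxPC-3 the count of 7 was 4 without 1E5 replicate 2, GW3965 replicate 2 or GW3965 replicate 3.

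The genes called by 1E5 and by 3A4 overlapped within a line. In MIA PaCa-2, 1649 genes moved the same way with both (883 higher and 766 lower, against 280 and 245 for independent lists) and 80 moved opposite ways. In PANC-1, 777 moved the same way (354 and 423, against 129 and 138) and 114 opposite ways. PPP1R15A rose with both in MIA PaCa-2 (7.86-fold and 3.61-fold), and LSS fell with both in PANC-1 (5.09-fold and 2.12-fold). In 5 simulations all groups of a line, DMSO included, were drawn without change and compared with the same simulated DMSO libraries, and the overlap was 0. Unchanged groups give few calls, so this was nearly fixed in advance and does not measure what shared DMSO libraries add. Since the 3 DMSO libraries of a line cannot be split, part of the excess may come from them. Across genes, which are not independent replicates, the log2 fold changes of 1E5 and 3A4 had r = 0.756 in MIA PaCa-2 (simulated 0.561), 0.403 in PANC-1 (0.486) and 0.36 in BxPC-3 (0.515). Their covariances were 1.43, 0.439 and 0.115 (simulated 0.127, 0.104 and 0.101). The overlap in MIA PaCa-2 was 919 without DMSO replicate 1, 886 without DMSO replicate 2, 635 without DMSO replicate 3 and 595 without 3A4 replicate 2. In PANC-1 it was 269, 442 and 315 without 3A4 replicates 1, 2 and 3 and 338 and 356 without DMSO replicates 2 and 3. Other fits gave 2777 in MIA PaCa-2 with all 36 libraries and 839 without the 2 shallowest, and in PANC-1 1349 with DESeq2 and 516 with no filter. The agonist shared 68 genes with 1E5 in direction in MIA PaCa-2 (6 opposite; 16.0 higher and 3.98 lower for independent lists) and 50 with 3A4 (3 opposite; 4.97 and 1.1). In PANC-1 it shared 4 with 1E5 (3 opposite; 1.58 and 0.193 for independent lists) and 0 with 3A4 (3 opposite; 0.283 and 0.0384), and in BxPC-3 0 with 1E5 and 1 with 3A4.

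Between lines, 2487 genes moved the same way with 1E5 in MIA PaCa-2 and PANC-1 (1255 higher and 1232 lower, against 752.5 and 714.5 for independent lists) of 3315 called in both. With 3A4 these numbers were 339 (203 and 136, against 40.55 and 40.87) of 357. HMOX1 rose in both with 1E5 (14.6-fold and 12.9-fold) and TK1 fell (8.84-fold and 5.66-fold). NAV2, UPP1 and H1-2 were higher with 3A4 in all 3 lines, where independent lists would give 0.014 genes, and no gene was called in all lines with 1E5. Besides the losses in BxPC-3 given above, the call in MIA PaCa-2 ended without 3A4 replicate 2 or DMSO replicate 2 for NAV2 (highest adjusted p = 0.0657) and for H1-2, which also lost it without DMSO replicate 3 (0.072) and without the 2 shallowest libraries. The response to 1E5 differed among lines for 8522 of 22132 genes, that to 3A4 for 1304 and that to GW3965 for 23 (1368 at an unadjusted p below 0.05). The count for GW3965 was 14 and 15 without GW3965 replicates 1 and 3 of BxPC-3 and 39 without GW3965 replicate 3 of MIA PaCa-2, and that for 3A4 was 588 and 715 without 3A4 replicate 2 and DMSO replicate 3 of MIA PaCa-2. For GW3965 it was 40 with limma-voom, 195 with DESeq2 and 36 without the 2 shallowest libraries, and for 3A4 it was 2564 with DESeq2, 640 after thinning and 797 without the 2 shallowest libraries. With 1E5 the test passed for all 23 mitosis genes, 23 of 25 DNA replication genes and 20 of 22 integrated stress response genes. SEMA3A, a guidance cue, was at 10.2 ± 1.12 CPM with 1E5 against 97.2 ± 8.41 in PANC-1, 165 ± 2.64 against 240 ± 30.0 in MIA PaCa-2 and 132 ± 4.56 against 131 ± 5.86 in BxPC-3 (interaction adjusted p = 1.88e-13). With 3A4, DHRS3, a retinal reductase, fell 3.33-fold in MIA PaCa-2 and rose 2.23-fold in PANC-1 (1.51e-06), and with GW3965 the test passed for 4 of 21 interferon response genes (8 adjusted over the list alone), such as USP18 (0.000105).

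**Figure D3:**
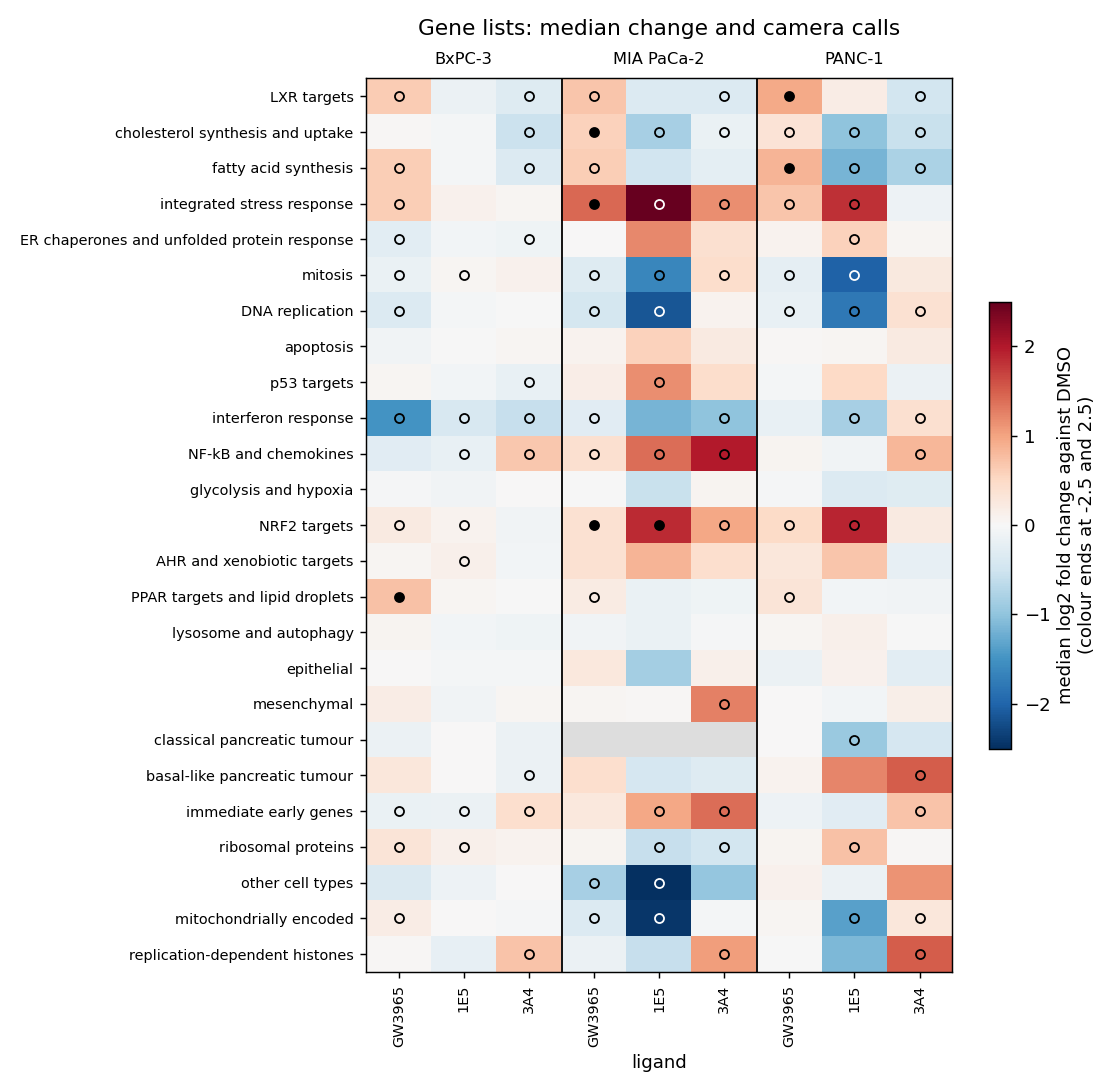
Median log2 fold change against DMSO of each gene list (colour) by ligand and line. A filled circle marks a camera adjusted p below 0.05 with both the preset and an estimated correlation, an open circle one with the preset correlation only, and grey a list with fewer than 3 measured genes.

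Some camera calls of lists not given above ended without 1 library. In BxPC-3 with GW3965 mitosis genes were lower (0 of 23; adjusted p = 0.00856, and adjusted p = 0.414 with an estimated correlation), a call that ended without GW3965 replicate 2 or DMSO replicate 3 (highest 0.112). With 1E5 there, 4 such lists had no member past the threshold over all genes. Mitosis genes were higher (0.00489; ended without 1E5 replicate 1 or DMSO replicate 2, highest 0.279). NF-kB and chemokine genes were lower (0.0419; DMSO replicate 1 or 3 or 1E5 replicate 2, 0.579). The others were NRF2 targets (higher, 0.00703; 1E5 replicate 1 or DMSO replicate 1, 0.258) and ribosomal proteins (higher, 0.000465; DMSO replicate 2, 0.0532). Their camera results were adjusted p = 0.375, 0.614, 0.345 and 0.579 with an estimated correlation. With 3A4 there, ER chaperones were lower (0.00908; DMSO replicate 1 or 3A4 replicate 3, 0.0839). So were p53 targets (0.0449; any library but 3A4 replicate 1, 0.11) and basal-like markers (0.0363; 3A4 replicate 1 or 2 or DMSO replicate 1, 0.138). These 3 lists had no member past the threshold over all genes either, with camera adjusted p = 0.214, 0.203 and 0.426 with an estimated correlation. With all 36 libraries in 1 fit the calls of mitosis with GW3965, NF-kB and chemokine genes with 1E5, and p53 targets and basal-like markers with 3A4 also ended. That of p53 targets ended after thinning and with the replicate block as well.

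In MIA PaCa-2 with GW3965 1 such camera call was that of interferon response (lower, 0 of 18; adjusted p = 0.0252; ended without DMSO replicate 1 or 3 or GW3965 replicate 2, highest 0.303). Others were PPAR targets and lipid droplets (2 of 9 higher, 0.012; GW3965 replicate 1 or DMSO replicate 2, 0.0588) and other cell types (1 of 6 lower, 0.0385; GW3965 replicate 2 or DMSO replicate 3, 0.397). The gene that fell in the last list was CD14, whose own edgeR call ended without any of the 6 libraries (highest 0.131), with limma-voom and without the 2 shallowest libraries. The 3 lists had camera adjusted p = 0.286, 0.141 and 0.31 with an estimated correlation. With 1E5 11 of 20 ribosomal protein genes fell and 1 rose (0.023; 1E5 replicate 2 or DMSO replicate 3, 0.0876). With 3A4, 6 of 22 cholesterol synthesis and uptake genes fell (0.0255; 3A4 replicate 3, 0.0787). These had camera adjusted p = 0.665 and 0.188 with an estimated correlation. Without the 2 shallowest libraries the calls of other cell types and of ribosomal proteins also ended, the former with no filter or all 36 libraries in 1 fit as well.

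In PANC-1 with GW3965 mitosis (0 of 23; 0.000966; ended without DMSO replicate 1 or 3 or GW3965 replicate 2, highest 0.621) and DNA replication genes (0 of 25; 7.17e-05; DMSO replicate 1 or GW3965 replicate 2, 0.678) were lower, with camera adjusted p = 0.639 and 0.579 with an estimated correlation. With 1E5 12 of 20 interferon response genes fell and 4 rose (0.0407; 1E5 replicate 2 or 3 or DMSO replicate 2, 0.0958), with camera adjusted p = 0.639 with an estimated correlation. With 3A4 DNA replication (1 of 25 higher; 0.000299; DMSO replicate 2, 0.0638) and interferon response genes (1 of 20 higher; 0.0268; 3A4 replicate 1 or 2 or DMSO replicate 3, 0.284) passed. So did mitochondrially encoded (3 of 13 higher; 0.0484; 3A4 replicate 1 or 2 or DMSO replicate 1, 0.178) and histone genes (2 of 5 higher; 0.0397; DMSO replicate 1 or 3A4 replicate 3, 0.142). These had camera adjusted p = 0.605, 0.614, 0.711 and 0.375 with an estimated correlation. With all 36 libraries in 1 fit the calls of interferon response with 1E5 and 3A4 and of mitochondrially encoded genes also ended. So did the last with no filter or the replicate block, and interferon response with 1E5 after thinning. Histone genes lost theirs with the replicate block or without the 1E5 libraries.

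Of the 222 tests of lists in the 9 contrasts against DMSO, 92 passed with the preset correlation. With an estimated correlation 7 of these held: PPAR targets and lipid droplets with GW3965 in BxPC-3, cholesterol synthesis and uptake, integrated stress response and NRF2 targets with GW3965 in MIA PaCa-2, NRF2 targets with 1E5 in MIA PaCa-2, and LXR targets and fatty acid synthesis with GW3965 in PANC-1. Apoptosis genes passed camera in none of 9 tests (lowest camera adjusted p = 0.07, with 1E5 in MIA PaCa-2, where 9 of 23 rose and 2 fell), nor did glycolysis and hypoxia (0.134; 3 of 19 higher and 8 lower there), lysosome and autophagy (0.0657) or epithelial genes (0.117). By fry each of these lists passed with 1E5 in MIA PaCa-2 (adjusted p = 7.31e-06, 0.00744, 0.00022 and 0.00309), towards higher, lower, higher and lower. Fry does not set a list against the other genes, and 47% of all genes tested were called in that contrast. Passing fry there therefore does not set these lists apart. With 1E5 in PANC-1 8 of 22 apoptosis genes rose and 4 fell (fry adjusted p = 0.0518). The median, the mean and the test of a list differed in sign in 34 of the 222 tests, none of them among the 92 that passed. The lowest adjusted p among these was 0.137, for NRF2 targets with 3A4 in PANC-1 (median 0.22, mean -0.0263, test towards higher).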

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

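The tests of ABCG1 levels against ABCA1 and of why no gene passed with 1E5 in BxPC-3 were devised only after those results were seen. For depth, a test added after the data had been seen, and for other arrangements of the labels, the predictions were written down before the result of the test was known.

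The results below stood out because the response to a ligand differed among the 3 lines in the edgeR interaction test. This held for 23 genes with GW3965, 8522 with 1E5 and 1304 with 3A4. With GW3965 the adjusted p of the genes named in the report was below 0.05 for ABCG1 (2.9e-05), IFIT1 (0.00725), ISG15 (0.00873), USP18 (0.000105) and S100P (0.00725). With 3A4 it was so for CXCL8 (0.000613), BIRC3 (0.0144), EGR1 (0.00853), IFIT1 (0.00139), BST2 (0.00103), RPL3 (0.00547), AKR1C1 (0.000418), NQO1 (0.00732), NEURL3 (9.64e-05), FADS2 (0.0124), ACLY (0.0426), TM7SF2 (0.00348), AREG (3.84e-05), S100A2 (0.00309), DHRS9 (0.00663), SPDEF (2e-04), PPP1R15A (0.0469) and DHRS3 (1.51e-06). With 1E5 it was so for KIF20A (1e-06), AURKB (1.46e-06), CDC45 (1.99e-08), TK1 (1.56e-08), MT-CO2 (6.89e-08), LSS (4.96e-07), HMOX1 (5.77e-09), PPP1R15A (4.88e-09), GCLC (1.14e-06), CDKN1A (1.9e-08), CXCL8 (8.34e-05), JUNB (2.44e-07), LCN2 (6.46e-09), LAMP3 (7.33e-09), CD14 (1.73e-06), CDH5 (0.00012), ABCG1 (0.000857), FASN (2.21e-06), SCD (0.00471), NR1H2 (0.018), KIF11 (4.48e-08), MCM10 (1.9e-07), MT-CYB (1.55e-08), FADS2 (2.88e-08), ACACA (7.74e-07), OSGIN1 (3.29e-08), HSPA5 (5.81e-11), RPS18 (2.2e-05), CYP1A1 (1.94e-05), PCDH20 (5.56e-05), AGR2 (1.08e-06), NR1H3 (0.0161) and SEMA3A (1.88e-13).

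The 6 libraries of 2 groups of a line can be divided 3 against 3 in 10 ways, the real division included, so the share of divisions that reach the real count is never under 0.1. At least as many genes as in the real division were called in 1 of the 10 for 11 contrasts and in 10 of the 10 for 1E5 in BxPC-3, whose real count is 0 (highest other 2). The real and the highest other counts in BxPC-3 were 239 and 2 with GW3965, 6 and 4 with 3A4, and 26 and 3 for 3A4 against 1E5. In MIA PaCa-2 they were 85 and 5 with GW3965, 7635 and 0 with 1E5, 2235 and 1 with 3A4, and 5262 and 2 for 3A4 against 1E5. In PANC-1 they were 9 and 2, 7248 and 1, 1367 and 4, and 6914 and 1 in the same order.

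For the difference among lines the labels of ligand and DMSO were exchanged within lines in 25 regroupings, the real one included. With 1E5 only the real one, 1 of 25, reached 8522 genes (highest other 5622). With GW3965, 6 of 25 reached 23 genes (highest other 54), and with 3A4, 2 of 25 reached 1304 (highest other 1645). A regrouping that exchanges all labels of 1 line turns a response that the lines share into a difference among them. Such regroupings are no measure of chance, so these shares do not decide whether chance accounts for any of the counts. Regroupings that kept or fully exchanged the labels of 1 or more lines gave 3 to 1645 genes for 3A4 (0 to 14 in the rest), 6 to 54 for GW3965 (0 to 15) and 0 to 5622 for 1E5 (0 to 1). This split was made after the counts were seen and its ranges overlap, so whether single lines set the counts was left open.

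The large counts in MIA PaCa-2 were weighed against depth, since its DMSO and GW3965 libraries were the shallowest. After every library was thinned at random to 2701393 counts, the median signed log2 fold change of the called genes was 0.994 times that before with 1E5, 0.995 times with 3A4 and 0.97 times with GW3965. Of the genes called before, 6839 of 7635, 2096 of 2235 and 84 of 85 were still tested, and 6330, 1740 and 76 genes were called in all. How many of the genes called after thinning had also been called before was not counted. Random thinning leaves the expected fold change of a gene as it was, so the ratios had little room to fall whatever the cause. A cause that goes with the shallow groups cannot be told from the ligands by this test. Whether the lines differ in biology, such as in receptor activity or uptake of the ligands, was not tested.

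No gene passed with 1E5 in BxPC-3, against 7635 and 7248 in the other lines. The median SE in BxPC-3 was 0.842 times the lower of the other lines, which argues against a larger spread over the line as a whole. That SE pools the spread of all groups of a line, so it cannot exclude a larger spread in the 1E5 or DMSO libraries alone. Cells that did not receive 1E5 could not be told from cells that did not respond. CYP1A1, an AHR target, had a log2 fold change of 2.31 ± 0.677 (edgeR adjusted p = 0.0437, adjusted over the list alone; 0.00534 unadjusted), but it was picked after its value was seen, so this decides nothing. A lower sensitivity of BxPC-3 to 1E5 remains open and was not tested.

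ABCG1 rose with 1E5 in MIA PaCa-2 and PANC-1 while ABCA1, a gene that GW3965 raised there as well, did not pass. RNA of GW3965-treated cells in the 1E5 libraries would raise both, but ABCA1 lay below the level predicted from the share needed for ABCG1 in 3 of 3 libraries of each line, by 25 ± 14.4 CPM in MIA PaCa-2 and 20 ± 11.1 CPM in PANC-1. In PANC-1 the values argue against such RNA as the cause. ABCA1 (11.2, 6.44 and 10.1 CPM, against 15.1, 25.9 and 11.2) and FASN (210, 403 and 179 CPM, against 264, 454 and 197) lay below even the least level that the lowest share brings by itself. That least level has no counting error attached, and the gaps in replicate 3 were small, so such RNA is not excluded there. SREBF1 and MYLIP lay above their least levels in every library, which such RNA would allow. In MIA PaCa-2 the values argue against it for replicate 3 alone (ABCA1 19.4 CPM, against 29.4), and for replicates 1 and 2 (9.29 and 14.6 CPM, against 5.8 and 10.9) it could not be decided. A regulation of ABCG1 apart from LXR was not tested.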

How the results depend on the processing

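Thinning to 1 depth, removal of mitochondrially encoded genes, leaving out the 2 MIA PaCa-2 libraries under 4e+06 counts (DMSO and GW3965 replicate 3) and leaving the 1E5 libraries out of the fits in MIA PaCa-2 and PANC-1 were added only after the data had been seen. No call turned into a call in the opposite direction. Changes of sign without a call are left out of that statement. There were 43 of them among named genes, and they were not tallied for gene lists. Of 327 results for named genes 264 were called. Of these, 183 kept their call under every alternative chosen beforehand and 81 lost it in some, while 11 other results gained one. Of 92 list calls 66 kept theirs, the estimated correlation aside, 26 lost it in some and 29 others gained one. Of the calls of named genes, 296 of 1584 were lost over the fits without 1 library, 35 of 262 with only the compared groups in the fit, 24 of 264 with all 36 libraries in 1 fit, 21 of 264 with limma-voom, 10 of 264 with no filter, 3 of 264 with RLE and 1 of 262 with DESeq2. Lost as well were 8 of 263 after thinning, 16 of 124 without the shallow libraries, 9 of 112 without 1E5 and 0 of 255 without mitochondrial genes. Without any scaling the median log2 fold change of all genes moved by 0.184 for 1E5 in MIA PaCa-2 and by less than 0.1 elsewhere. At the depth and spread of these libraries edgeR recovered 39% to 44% of simulated 2-fold changes in MIA PaCa-2, 50% to 61% in PANC-1 and 62% to 64% in BxPC-3. The genes changed in these simulations had at least 2 CPM with DMSO.

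Counts of genes moved by more than 1.5 times as follows, and except where fewer libraries or genes in the fit account for it the cause was not tested. With all 36 libraries in 1 fit, GW3965 called 110 genes in BxPC-3, 192 in MIA PaCa-2 and 19 in PANC-1. This fit called 11 genes for 3A4 and 9 for 3A4 against 1E5 in BxPC-3, 3820 for 3A4 in MIA PaCa-2 and 2777 there the same way by 1E5 and 3A4. DESeq2 called 599, 264 and 99 genes with GW3965, 12 with 1E5 and 365 with 3A4 in BxPC-3, 486 for 3A4 against 1E5 there, 2564 with 3A4 in PANC-1, and 3 in BxPC-3 and 1349 in PANC-1 the same way by 1E5 and 3A4. For differences among lines it called 195 with GW3965 and 2564 with 3A4. Limma-voom called 14 genes with 3A4 in BxPC-3, 18 with GW3965 in MIA PaCa-2 and 40 for differences among lines with GW3965. With only the compared groups the counts were 90 for GW3965, 1 for 1E5 and 9 for 3A4 against 1E5 in BxPC-3, 22 for GW3965 in MIA PaCa-2 and 2403 for 3A4 in PANC-1. With no filter 3A4 called 903 genes in PANC-1, 516 of them shared with 1E5. Without the 1E5 libraries GW3965 called 41 in MIA PaCa-2 and 15 in PANC-1, and 3A4 3020 in PANC-1. Without the shallow libraries 3A4 called 1085 in MIA PaCa-2, 839 of them shared with 1E5, and differences among lines numbered 36 for GW3965 and 797 for 3A4 (640 for 3A4 after thinning).

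Without 1 library the counts ranged as follows. In BxPC-3 they were 68 to 151 with GW3965, 0 to 4 with 1E5, 0 to 7 with 3A4, 0 to 39 for 3A4 against 1E5, and 4 to 6 for LXR targets of 1E5 against GW3965. In MIA PaCa-2 they were 16 to 85 with GW3965, 749 to 2497 with 3A4, and 595 to 1939 the same way by 1E5 and 3A4. In PANC-1 they were 4 to 35 with GW3965, 429 to 971 with 3A4, and 269 to 832 the same way by both. For differences among lines they were 14 to 39 with GW3965 (14 without GW3965 replicate 1 and 15 without replicate 3 of BxPC-3, 39 without GW3965 replicate 3 of MIA PaCa-2) and 588 to 1931 with 3A4 (588 without 3A4 replicate 2 and 715 without DMSO replicate 3 of MIA PaCa-2). The counts for 1E5 in MIA PaCa-2 (6393 to 6853) and PANC-1 (5658 to 7789) stayed within 1.5 times.

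The replicate numbers were not taken to pair the samples, since not every pair of same-numbered libraries correlated above 0.1. Over 18 pairs per line the lowest correlation was 0.0215, -0.0624 and -0.0237 in BxPC-3, MIA PaCa-2 and PANC-1. The medians were 0.0899, 0.0579 and 0.0621, against -0.0614, -0.0302 and -0.0333 for different numbers, and 12, 9 and 12 of 12 libraries correlated best with their own number, a hint that they share a source which the labels do not name. With the replicate block 5 of 264 calls of named genes and 3 of 92 list calls were not made. The counts with it in BxPC-3 were 478 for GW3965, 275 for 3A4 and 412 for 3A4 against 1E5, and for differences among lines 52 for GW3965 and 2053 for 3A4.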

Other observations

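The genes below and the levels by library were chosen after their values were seen. SMAD4, a tumour suppressor of TGF-beta signalling, had 0 counts in the 3 DMSO libraries of BxPC-3, which a count of 0 limits to 0.0409 CPM, against 52.5 ± 16.1 CPM in MIA PaCa-2 and 45.9 ± 5.78 CPM in PANC-1. CDKN2A, a cell cycle inhibitor, had 0 counts in the DMSO libraries of all 3 lines (limits 0.0409, 0.149 and 0.0424 CPM). Genes called alike by 1E5 in MIA PaCa-2 and PANC-1, 2487 in all, had a median signed log2 fold change of 0.0315 in BxPC-3, where 59.8% went the same way, against 1.24 and 0.961 in the lines that defined them. The 339 such genes of 3A4 had a median of 0.248 in BxPC-3, with 88.5% the same way.

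SCD was lowest in replicate 1 of all 4 groups of BxPC-3 (1334, 5246, 600.5 and 495.8 CPM with DMSO, GW3965, 1E5 and 3A4). In PANC-1 it was highest in replicate 2 of all 4 groups (11540, 25040, 3298 and 2521 CPM). Counts from mitochondrial rRNA genes took 1.83% ± 1.07 of the PANC-1 libraries with 1E5 against 0.726% ± 0.105 with DMSO, and 1.03% ± 0.278 against 1.57% ± 0.231 in MIA PaCa-2. The mean in PANC-1 with 1E5 was raised by replicate 2, at 3.06%, against 1.12% and 1.32% in replicates 1 and 3.

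The readthrough gene PEDS1-UBE2V1 had 0 counts with DMSO in MIA PaCa-2 and held 35.9% of the counts of its locus with 1E5 and 40.1% with 3A4. The sum of the locus was 173 ± 7.19 CPM with DMSO, 184 ± 7.78 with 1E5 and 161 ± 4.39 with 3A4. INO80B-WBP1 held 50.7% of its locus with 3A4 in PANC-1 and 0 with DMSO, at sums of 40.7 ± 2.41 and 51.1 ± 10.2 CPM. How counts are divided between such genes and their partners is uncertain, and they are left out of the report.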
